A study of Solanum lycopersicum with 2 samples.

How the data were processed

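The series holds 2 digital gene expression (tag) libraries from floral buds of tomato (Solanum lycopersicum, cultivar Micro-Tom), 1 from a SlREV overexpression line and 1 from wild type. Per the labels' protocols, RNA of 3 plants was pooled per genotype, cDNA was made on oligo(dT) beads and cut with NlaIII at CATG, an adaptor was ligated to that end, and MmeI then cut 17 bases downstream. A second adaptor was ligated to the MmeI end, and the tags were amplified by PCR and sequenced on an Illumina HiSeq 2000. The labels describe no molecular identifiers, so copies are sequenced tags and not independent molecules, and intervals cover counting error only.

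Each deposited file lists distinct tags of 21 bases with a copy count and a TPM value, per the file headers. The count is the raw number of copies of that tag. The TPM column deposited by the authors equals the copy count scaled to the total of the same file, within rounding (largest difference 0.0050). It is not corrected for transcript length. The lowest listed count is 2, and how tags seen once were removed, how reads were filtered and whether tags were matched to genes are not given in the sources used here. A tag not listed in a library was therefore taken as 0 copies and could have had 1. At these depths 1 copy was 0.215 TPM in overexpression and 0.208 TPM in wild type.

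Groups were taken from the genotype labels. No transcript or genome sequence was used here, so tags were not matched to genes. The comparisons per gene that had been planned (all genes, class III homeodomain-leucine zipper genes and gene lists by function) were not run, and the planned comparison per tag is the main result. Tags with at least 10 copies summed over both libraries were tested. The test was the exact binomial test of the copies in one library given the sum, with the expected share from the library totals, two-sided as double the smaller tail, with Benjamini-Hochberg adjustment. A tag was called at an adjusted p of 0.001 or less and a ratio of 2-fold or more. With 1 library per genotype there are no residual degrees of freedom, and the test compares 2 libraries. For the log2 ratio, 0.5 copy was added to both libraries. Folds have exact (Clopper-Pearson) 95% intervals, shares have Wilson 95% intervals, and a fold against a tag not listed is a lower bound taken against 3 copies in that library. This bound ignores the counting error of the listed library and is higher than the lower end of the two-sided 95% interval used to rank tags, for example 962 against 782 for CATGTGTTGAGCATATAAGAA.

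Named tags followed a rule fixed before the data were examined: the 10 called tags per direction with the largest lower bound of the 95% interval of the fold, and the 3 most abundant tags of each library. The rule's requirement of a functional description was dropped, since tags carry none. Some of the tags that the rule picks are not reported here. Tags of vector parts were made by taking 21 bases at each CATG site of the nopaline synthase terminator, the CaMV 35S terminator and the nptII coding sequence (4 sites). These sequences were written down from general knowledge and not taken from a database, and were fixed before their counts were looked up.

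The tag sequence model was a least-squares fit of the log2 ratio on indicators of each base at each of the 17 positions after CATG, in tags with at least 50 summed copies. It was judged in 10 parts, each predicted from the other 9, and against 100 permutations of the ratios. In a correction, its prediction replaced a ratio of 1 as the expected value of the test. Pairs of tags taken as coming from 1 transcript were found in 2 ways. Neighbouring tags had to share at least 15 bases where the first holds a CATG site at which the second begins, so their sites lay 4 to 6 bases apart. Tail tags had to end in 4 or more A and share all bases before that run, at least 15, with a tag that ends in fewer than 3 A. The runs of paired tail tags were therefore 4 to 6 bases long. Medians have intervals from 2000 bootstrap draws over tags or pairs.

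Alternatives were TMM and median-of-ratios scaling, totals without the 20 most abundant tags, other filters, thresholds and pseudocounts, 1 copy for tags not listed, removal of a GC trend or of position terms, removal of tags ending in A, merging of 1-base variants, and edgeR exact tests with an assumed biological coefficient of variation of 0.2 or 0.4. The test was tested on simulated data drawn with counting error only from the real tags and totals, with 200 changed tags of at least 100 copies. Over the 55918 simulated tags tested, it called 42% of tags changed 2-fold, 98% of those changed 4-fold and 100% of those changed 8-fold, and 0 of 55718 unchanged tags. The simulation held no variation between plants or libraries and no effect of tag sequence. The last count therefore gives no rate of false calls for the real libraries. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 (size factors only).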

Results

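Early floral buds of tomato were compared between plants that carry a SlREV transgene and wild-type plants. SlREV is the tomato relative of REVOLUTA, a class III homeodomain-leucine zipper transcription factor known for its part in organ polarity, meristems and vascular tissue. The line, labelled 35S::SlREVRis-1, carries a microRNA-resistant SlREV transgene under the CaMV 35S promoter, a strong plant promoter of viral origin. The question was which transcripts differ in abundance between buds of this line and buds of Micro-Tom, the dwarf cultivar in which it was made. Each genotype was measured once, in 1 tag library made from RNA pooled from 3 plants, so no difference given here has a replicate check. In this assay NlaIII cuts cDNA at CATG, and each transcript is read as a tag of 21 bases that begins at a CATG site, usually the one nearest its 3′ end. The overexpression library held 4646494 tag copies over 106917 distinct tags, and the wild-type library held 4815849 copies over 107483 distinct tags. Neither library listed a tag with fewer than 2 copies. Tags were not assigned to genes or to genome positions, since no transcript sequences were used here, so SlREV itself is not analysed here and the items below are tags.

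The transgenic library carried tags of plant transformation vectors and the wild-type library listed none of them. Terminators are the vector segments at which transgene transcripts end, so their tags show whether a library holds transgene RNA. The tag at the CATG site of the CaMV 35S terminator, CATGTGTTGAGCATATAAGAA, had 2785 copies (599 TPM) in the overexpression library and was not listed in wild type, at least 962-fold higher. The tag at the 3′-most CATG site of the nopaline synthase terminator, CATGACGTTATTTATGAGATG, had 864 copies against none listed, at least 298-fold higher. The next site upstream in that terminator gave CATGTAATGCATGACGTTATT with 294 copies, at least 102-fold higher, and the site farthest upstream gave CATGTAATAATTAACATGTAA with 7 copies, too few to be tested. Together the 4 terminator tags had 3950 copies (850.1 TPM) in the overexpression library and 0 in wild type, where 3 copies would have been 0.623 TPM. Each bound was taken against 3 copies in the wild-type library. The terminator sequences were written down from general knowledge of these vector parts before the counts were examined, and the construct map was not used here.

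Of 55222 tags with at least 10 copies summed over the libraries, 12511 differed between them at 2-fold or more, with 7463 higher and 5048 lower in the overexpression library. These calls came from an exact two-sided binomial test of copies with Benjamini-Hochberg adjusted p of at most 0.001. The test compares these 2 libraries, not the genotypes, and covers counting error only. Of the called tags, 6131 differed 4-fold or more (3906 higher, 2225 lower) and 1134 differed 16-fold or more (753 higher, 381 lower). The log2 ratios of tested tags had an SD of 1.65 and a median of 0.14. Among the 1376 tags with 1000 or more summed copies, the SD was 1.34, against a median counting SD of 0.074, and 645 were called (295 higher, 350 lower). Across tested tags, which are not independent replicates, log2(TPM + 1) of the libraries had a Pearson r of 0.78 and TPM a Spearman rho of 0.65. Calls depended on how much replicates are assumed to vary. An edgeR exact test with an assumed biological coefficient of variation of 0.2 called 3585 tags, and one with 0.4 called 6. Those 6 were the CaMV 35S terminator tag, both nopaline synthase terminator tags named with over 200 copies, 2 forms of the latter that end in A, and a tag with PstI and SalI sites; the wild-type library listed none of them.

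**Figure D1:**
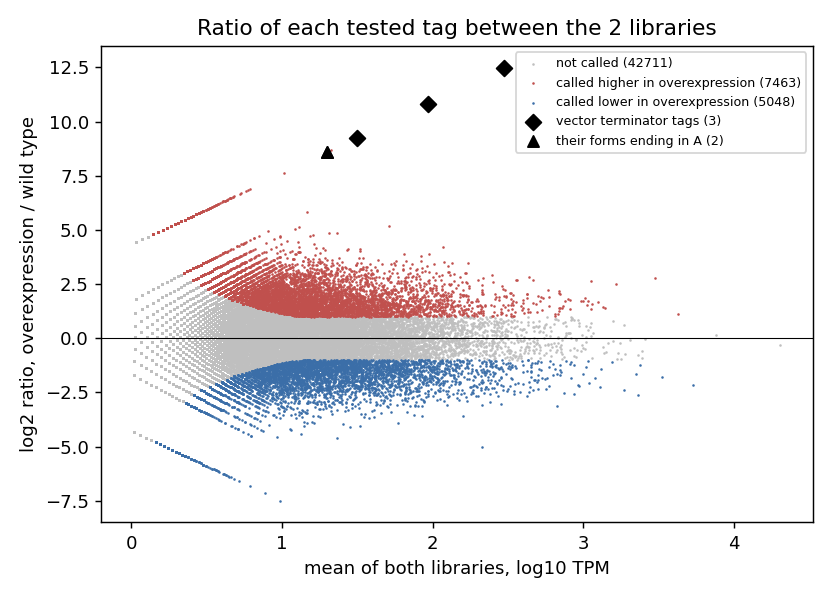
Each point is 1 of the 55222 tested tags, placed by its mean TPM over both libraries (log10) and by its log2 ratio of overexpression to wild type, with 0.5 copy added to each library; colours mark the 7463 tags called higher and the 5048 called lower. The 3 tested vector terminator tags (diamonds) and 2 forms of them that end in A (triangles) lie at the top of the plot, and the outermost diagonal lines of points are tags listed in 1 library only, whose ratio depends on the added 0.5 copy.

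The tags with the largest increases were led by vector sequence and by tags rich in A and T. Besides the 3 terminator tags, the 10 highest included CATGACGTTATTTATGAAAAA (186 copies against none listed, at least 64.3-fold) and CATGACGTTATTTAAAAAAAA (185 copies, at least 63.9-fold). Both follow the nopaline synthase terminator, for 16 and 13 bases, and then run into A. CATGCCTGCAGGTCGACTCTA had 196 copies and was at least 67.7-fold higher, and it holds recognition sequences of PstI and SalI, enzymes used in cloning. CATGTGTTTCTTAATAAAATT (96 copies, at least 33.2-fold) and CATGATAGTTCCACAAAAAAA (57 copies, at least 19.7-fold) were also not listed in wild type. CATGTAATGTTTGTTAAAAAA had 466 copies against 13, 37.2-fold higher with an exact 95% interval of 21.5 to 70.3. CATGAGAAGTATGATTTTTAA had 135 copies against 2, 69.96-fold higher with an interval of 19.0 to 584. The excess of CATGTAATGTTTGTTAAAAAA fell from a log2 ratio of 5.16 to 2.92 when terms for the base at each tag position were removed, still past the threshold.

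The tag with the firmest decrease was CATGGAAAATTTGTGGTTTCC, with 59 copies (12.7 TPM) in the overexpression library and 2004 (416 TPM) in wild type. It was 32.8-fold lower, with an exact 95% interval of 25.3 to 43.2. CATGATTTTTGCAGCTATATT fell from 530 to 34 copies, 15.0-fold (10.6 to 21.9), and CATGACTTGGAAGCATATTTG from 217 to 8 copies, 26.2-fold (13.05 to 61.4). Other large decreases were of tags not listed in the overexpression library. CATGGAAAGAACAAAACACAC had 93 wild-type copies, at least 29.9-fold more than in the overexpression library, and CATGAAATATTTTTCGAAGTT had 74, at least 23.8-fold more. None of these 5 tags ended in more than 1 A, and each stayed past the threshold when terms for the base at each tag position were removed. None was called by the edgeR exact test with an assumed coefficient of variation of 0.4.

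Among the most abundant transcripts the libraries shared their leading tag. CATGTGTATTTGACAAAATCT was first in both, with 84399 copies (18164 TPM) in overexpression and 108534 (22537 TPM) in wild type. It was 1.24-fold lower in overexpression, under the 2-fold threshold, but at a log2 ratio of -1.08 it passed the threshold once terms for the base at each tag position were removed. CATGAATAAGAAACTTCCAAT had 8042 TPM in overexpression and 7148 TPM in wild type, a ratio of 1.12 that was not called and whose sign turned when a trend on GC content was removed (log2 ratio 0.17 before, -0.58 after). CATGGGTCAGAATCATTGGAT, the second most abundant wild-type tag, fell from 8775 to 1960 TPM, 4.48-fold (4.38 to 4.58). Its log2 ratio of -2.16 moved to -0.93, under the threshold, when terms for each pair of neighbouring bases were removed. CATGTTGTTGGTTTCTGTTCC, the third most abundant overexpression tag, was 2.18-fold higher (2.14 to 2.23), at 5850 against 2679 TPM. With TMM scaling its log2 ratio was 0.995, just under the threshold, and the edgeR exact test with an assumed coefficient of variation of 0.2 did not call it (adjusted p 0.0303).

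Tags that end in a run of A, as a tag does when it reaches the poly(A) tail, were higher in the overexpression library as a class. Tags ending in 5 or more A made up 5.19% of copies in overexpression (Wilson 95% interval 5.17 to 5.21) and 1.02% in wild type (1.01 to 1.03). Of 3634 such tags tested, 1854 were called higher and 9 lower. Of 51588 other tags, 5609 were called higher and 5039 lower. The median log2 ratio was 2.51 for the class (bootstrap 95% interval 2.44 to 2.58 over 1041 tags with 50 or more copies) and 0.085 for the others. With tags ending in 4 or more A left out, 5336 tags were called higher and 4972 lower. The class was chosen after the values were seen.

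**Figure D2:**
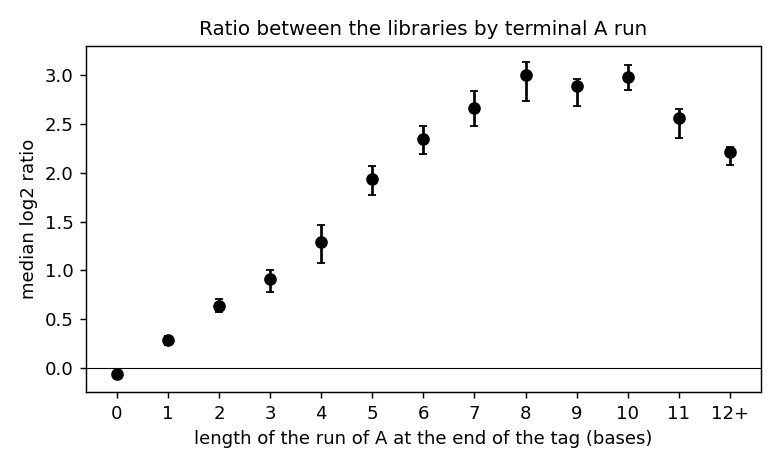
The median log2 ratio of overexpression to wild type (vertical axis) is plotted against the length in bases of the run of A that ends the tag, for tags with 50 or more summed copies; bars are bootstrap 95% intervals of the median over tags. The median was -0.06 without a final A, 1.94 at 5 bases and 2.996 at 8 bases.

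The ratio of a tag also followed its base composition and the bases at its ends and at some inner positions. G and C made up 33.0% of the 17 bases after CATG in overexpression and 37.1% in wild type, weighted by copies. Tags with 0 to 4 G or C had a median log2 ratio of 0.98 and tags with 9 or more a median of -0.65. Tags whose first base after CATG was T had a median of 0.86, with 4357 called higher and 483 lower. Tags with G there had a median of -0.51, with 842 called higher and 1916 lower. T at that position made up 44.8% of copies in overexpression and 30.4% in wild type. A linear model with a term for each base at each position predicted 41.6% of the variance of the log2 ratio in tags left out of its fit (22157 tags with 50 or more copies). Fitted to the 20275 of these without a run of 3 or more A at the end, it predicted 35.6%. After the removal of the terms fitted to all 22157 tags, 6761 tags were called, 3160 higher and 3601 lower, and 4501 of them had been called in the same direction before. After the removal of a GC trend 10142 tags were called, 4534 higher and 5608 lower, of which 7612 had been called in the same direction before, so that 44.7% of calls were higher in place of 59.7%.

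**Figure D3:**
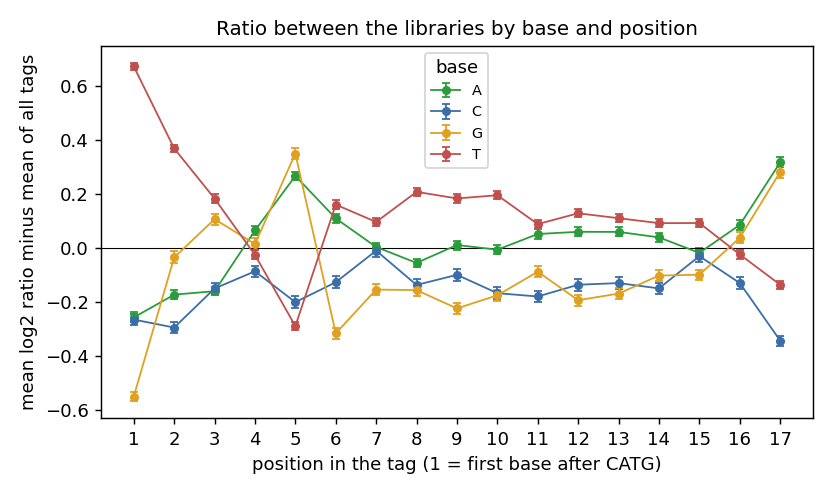
For each base at each of the 17 positions after CATG, the plot gives the mean log2 ratio of overexpression to wild type minus the mean over all tags (vertical axis), for 20275 tags with 50 or more copies and fewer than 3 A at the end; bars are standard errors over tags. T lies 0.67 above and G 0.55 below the mean at position 1, and A lies 0.32 above and C 0.34 below it at position 17. Inner positions differ too, with G 0.35 above and T 0.29 below the mean at position 5.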

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

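TMM scaling and the filter of 50 copies were chosen for tags before the data were examined, the other scalings, filters, thresholds and assumed variations had been planned for genes and were carried to tags, and the tag sequence corrections, the removal of tags ending in A, the merging of variants and the value of 1 copy for unlisted tags were chosen after the data were seen. The count of 12511 called tags (7463 higher, 5048 lower) stayed within 1.5 times under both other scalings, the total without the 20 most abundant tags, both filters, the 1.5-fold threshold, the larger pseudocount, 1 copy for unlisted tags, merged variants and the removal of tags ending in A. TMM moved the median log2 ratio of tested tags from 0.14 to 0.0051 and the share of higher calls from 59.7% to 51.5%. A 4-fold threshold gave 6131 calls (3906 higher, 2225 lower) and an adjusted p of 0.05 gave 20075 (11709 higher, 8366 lower), by construction. Removal of the GC trend left 10142 calls, with 4534 higher. Removal of the base terms per position left 6761 (3160 higher, 3601 lower), 19 of them opposite to the original call, and removal of terms for neighbouring bases left 5767 (2668 higher, 3099 lower). The edgeR exact test gave 3585 calls (2173 higher, 1412 lower) with an assumed variation of 0.2 and 6 (6 higher, 0 lower) with 0.4; no estimate of that variation can be had from 1 library per genotype. Of the 24 tags followed (picked by the rule for named tags, or of a terminator), none that was called changed sign under an alternative that tested it (21 were tested with the filter of 50 copies and 20 without tags ending in A, all 24 under the others), while 16 lost their call with an assumed variation of 0.4 and 1 each with TMM, the 4-fold threshold, an assumed variation of 0.2 and the removal of terms for neighbouring bases. No paired analysis was possible because each genotype has 1 library.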

Other observations

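The tests on terminator tags, nptII, GC content, sequencing errors and neighbouring sites were set before their results were seen, while those on swapped labels, the polylinker, bases at fixed positions, tags ending in A and the centred share of neighbouring tags were chosen afterwards. Besides the full tag at the 3′-most CATG site of the nopaline synthase terminator (864 copies), 2 forms of that tag ran into A after 16 and 13 bases, with 186 and 185 copies and none listed in wild type. The tags with 20 or more copies in one library that were not listed in the other numbered 200 in overexpression, of which 132 ended in 4 or more A, and 117 in wild type, of which 1 did. Among the 68 and 116 that did not end so, 0 pairs differed by a single base across the libraries, so no single-base variant between the plants was seen among them.

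The first pattern is the set of tags seen in the overexpression library only, 200 of them with 20 or more copies. Transcripts that end in a binary vector terminator are a candidate source of a few of these. Of the 4 terminator tags, 3 had 20 or more copies there, as did 2 forms that end in A, and none was listed in wild type. The source of most of the other tags was not tested. Swapped labels are argued against by the 0 copies of terminator tags in the library labelled wild type. A cloning polylinker cannot be told apart from another source of the 1 tag holding PstI and SalI sites, as that tag was noticed for its 196 copies in overexpression against 0 in wild type. For a kanamycin resistance gene, 0 of 4 nptII tags were listed in either library, the outcome set beforehand for the case without this source. That outcome cannot decide between this gene and another marker. The nptII sites would lie upstream of a terminator's. In the nopaline synthase terminator copies fell from 864 at the 3′-most site to 294 and 7 at the sites upstream. Farther sites could therefore lie under the 2 copies needed to be listed.

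The second pattern is the breadth of the difference, with 22.7% of tested tags called. Sequencing errors are argued against, since 0.36% of called tags lay 1 base from a tag at least 50 times as abundant. GC content as the whole cause is argued against too, since calls before the trend was removed were 1.23 times those after. Of the 12511, 7612 kept their call in the same direction, 0 were called in the opposite one, and the rest lost their call. A part of GC content in the pattern stays open, as higher calls fell from 7463 to 4534 and 2530 calls were new. Bases at fixed positions predicted 41.6% of the held-out variance, against at most -0.11% in 100 permutations. In tags without a run of 3 or more A at the end they predicted 35.6%. T exceeded G at the first position by 0.27 to 1.18 in median log2 ratio at each GC content from 3 to 9 of 17. Such an effect of position could come from a difference between the libraries in ligation, amplification or reading of tags. The 81 pairs of neighbouring sites, all 4 to 6 bases apart, also favoured the upstream tag in overexpression by a median log2 of 0.92 (0.54 to 1.15). With the position terms removed this median was 1.10 (0.80 to 1.41), so those terms did not account for the shift. Less complete NlaIII cutting in that library would favour the upstream tag, but sites farther apart were not covered. Differences of the RNA were not favoured by the test set beforehand. Tags of these pairs had the same sign in 63.3% of the 49 pairs with a call (49.3 to 75.3), an interval that holds an even split. The upstream shift itself lowers that share. Once each side was centred, a step chosen after the values were seen, the share was 75.5% (61.9 to 85.4). Tags of a pair also share at least 15 bases, and the ratio followed base composition. An effect of tag sequence could therefore raise either share above an even split without a difference of the RNA. Neither share decides the question, differences of the RNA stay open, and genotype and library preparation coincide in this design.

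The third pattern is the excess of tags ending in A. In the tail pairs, which hold runs of 4 to 6 A only, 314 of 336 tail tags exceeded the tag with the same first 15 bases. The median log2 difference was 1.23 (1.10 to 1.33). For those runs this argues against more RNA from genes with a CATG site near the tail as the whole cause. Longer runs, with a median log2 ratio of 2.996 at 8 bases, had no such pairs. A part of that cause stays open, as the log2 ratios of the 2 tags correlated across the pairs (Pearson r 0.72), though they also share the bases at those positions. An equal effect of A-rich sequence wherever it lies is argued against by tags with an inner run of 5 or more A, whose median log2 ratio was 0.0021 (-0.17 to 0.16). That median was not corrected for the base at each position, so a part of A-rich sequence stays open. The position terms, fitted to tags without an A run, left a median log2 difference of 0.75 (0.67 to 0.81) in the tail pairs. They so do not account for all of the difference in those pairs. A change in the use of poly(A) sites in the transgenic buds and a difference in how the libraries kept tags that reach the tail both stay open and were not tested.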
